A study of Homo sapiens with 8 samples.

How the data were processed

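Gene expression was measured by RNA sequencing in 8 libraries of RD-ES cells carrying doxycycline-inducible USP6, in 4 groups of 2 replicates given by the labels. Per the labels' protocols, RNA was extracted with trizol and libraries were made with a kit for stranded total RNA. The deposited table holds read counts, whole numbers without normalisation, for 34917 transcripts under 22257 gene symbols. Per the submitters' processing notes CASAVA 1.8.2, edgeR and the build hg19 were used. Their roles, the aligner, the counting method and whether counting used strand are not given in the sources used here. The deposited table also marks 1 transcript for each of 20843 symbols in a column with no stated unit, and no row lacked a gene name. No coordinates are given, since the reference at hand is of another build, GRCh38, and was used only for gene types, GC content and transcript length. Of the symbols 22128 matched it.

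Counts came per transcript, and 30.36% of symbols had several rows. Rows of 1 gene mostly held the same reads: among 2455 symbols with 2 rows and at least 1000 reads, the smaller row had at least 95% of the larger in 75.27%, and the 16 rows of VEGFA held between 1387 and 1443 reads in untreated replicate 1. Summing rows had been planned before the data were examined. Because it would count the same reads repeatedly, the row with the highest total per symbol became the main unit before any test was run, and the sum became an alternative. The chosen rows held 57.07% of the reads summed over all rows. Their totals ranged from 9304565 to 11984203 reads per library.

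Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with trimmed mean of M values normalisation (factors between 0.978 and 1.026), the default filter on low counts, and 1 mean per group. All 8 libraries entered 1 fit, which left 4 residual degrees of freedom, a prior of 6.9 and a common biological coefficient of variation of 0.097. The filter left 14601 genes. Calls had a Benjamini-Hochberg adjusted p under 0.05 without a minimum fold change. Standard errors were derived from the log2 fold change and the F statistic. The 6 contrasts were interferon without and with doxycycline, doxycycline without and with interferon, their interaction, and both treatments against none. Fold changes used the fit. For groups with 0 reads a lower bound against a floor of 3 reads over the group was given, and for 1 to 3 reads the ratio with an exact 95% binomial interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The total time on doxycycline is not stated for cells without interferon, so exposure may differ between groups.

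Of 28 gene lists written down before the data were examined, 25 had the 5 tested members needed for a set test. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, and again with an estimated correlation and with fry. With an estimated correlation the lists that kept their call in every single-treatment comparison were interferon-stimulated genes, JAK-STAT, IRF and GAS-type targets, NF-kB targets and chemokines. Lists share members: for example CXCL9, CXCL10 and CXCL11 are both chemokines and IRF and GAS-type targets. The choice of groups, tests, lists, named genes and most alternatives was made before the data were examined.

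Named genes followed a rule. USP6 came first. In each single-treatment comparison the 10 highest and 10 lowest log2 fold changes were taken among genes called, with a mean of at least 1 CPM and the same sign in both pairs of equal replicate number, leaving out pseudogenes. The interaction used the same rule without the sign condition. From each list described, the 4 members with the smallest p were added, always with TNFSF10, TNFRSF10A, TNFRSF10B, JAK1, STAT2, STAT3 and IRF9. Members named in a comparison outside that rule, such as MX1 and OAS2 with doxycycline in interferon-treated cells, were chosen after their values were seen. A single gene that the rule names is not reported here, though it stays in the tests and in the counts of calls and list members.

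Alternatives were size factors by relative log expression, DESeq2 1.42.0, no filter and a stricter filter (mean of 1 CPM and 50 reads), only the groups compared, replicate number as a block, summed rows, a minimum of 2-fold, other prior counts, and leaving out each library in turn. A lone library left in a group was then assumed to vary like the other groups. A crossed block, the transcript rows marked in the deposited table, and a correction of each library's trend with GC content and transcript length (loess, span 0.3) were added after seeing the data. GC content was known for 99.1% of tested genes.

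The scripts were tested on simulated data drawn from the means of the untreated libraries and the real library sizes. Genes were drawn independently and without a trend with GC content, and changed genes had a mean of at least 1 CPM. The rates below may thus not hold for the real libraries, and recovery does not cover genes under that level. For interferon without doxycycline, over 5 draws on 14325 to 14348 genes with 200 changed, edgeR recovered 78.2% of 2-fold and 96% of 4-fold changes, and 7.4% of its calls were unchanged genes, above the nominal 5%. DESeq2 recovered 75.4% and 92.6%, with 9.1% unchanged genes, on 14601 genes. A comparison with nothing changed gave at most 4 calls. Groups of 2 replicates were too small for tests of single outlying libraries or of other splits of the samples.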

Results

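RNA was sequenced from RD-ES, a Ewing sarcoma cell line, carrying a stably introduced USP6 gene that doxycycline switches on. USP6 is a ubiquitin-specific protease and an oncogene. The cells were a pool, not a single clone. The 8 libraries fell into 4 groups of 2 replicates: untreated, interferon alpha alone, doxycycline alone, and doxycycline with interferon. Doxycycline was given for 24 h before interferon, which was used at 1000 U/mL for 24 h. How long cells without interferon stayed on doxycycline is not stated. The comparison of both treatments with doxycycline alone, and the interaction, may thus include a difference in exposure. The stated purpose was to learn how USP6 and interferon, alone or combined, change gene induction. No doxycycline-treated cells lacking the transgene were among the samples analysed here, so effects of doxycycline itself and of USP6 cannot be separated. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

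The rows used for the 22257 gene symbols held 10354673 and 11249185 reads in the untreated libraries, and 9983126 and 10593945 with interferon. They held 11984203 and 11473648 reads with doxycycline, and 10158118 and 9304565 with both treatments. A floor of 3 reads per library corresponded to between 0.25 and 0.322 CPM, the read count scaled to a library of fixed size. Counts of replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom between 4.02 and 8.26, so no library was counted as a duplicate. The first principal component held 51.5% of the variance and placed the untreated libraries at -40.1 and -34.6 and those with both treatments at 47.4 and 31.5. Levels below are mean CPM ± SD (n = 2 libraries per group), changes are log2 fold changes ± SE, and "edgeR adjusted p" is the Benjamini-Hochberg adjusted p of the edgeR quasi-likelihood test over 14601 genes.

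Libraries also differed in their relation to GC content. Across genes, which are not independent replicates, the deviation of a library from the gene's mean correlated with GC content with a Spearman's rho of 0.59 and 0.12 in the untreated libraries and 0.32 and 0.04 with interferon. The values were -0.49 and 0.35 with doxycycline and -0.65 and 0.06 with both treatments. Among genes without a call, the log2 change fell with GC content in the comparisons of single treatments, with a rho of -0.29 for interferon, -0.42 for doxycycline, -0.32 for interferon in doxycycline-treated cells and -0.46 for doxycycline in interferon-treated cells.

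USP6 itself was read at 9.32 ± 0.783 CPM in untreated cells and 9.75 ± 0.816 with interferon. It rose to 563.4 ± 7.4 CPM with doxycycline, a log2 change of 5.92 ± 0.12 (edgeR adjusted p = 3.6e-10). With both treatments it stood at 392.9 ± 22.6 CPM. In doxycycline-treated cells the USP6 count fell with interferon by 0.52 on the log2 scale (SE 0.08, edgeR adjusted p = 0.0044), while without doxycycline its change was 0.07 ± 0.14 (edgeR adjusted p = 0.89). The difference between these responses did not pass the test (edgeR adjusted p = 0.91). USP6 shares sequence with USP32 and the TBC1D3 family, so reads could be split between these genes and the USP6 value is uncertain to that extent. USP32 was not called for any single treatment, and its change with both treatments was 0.39 ± 0.08 (edgeR adjusted p = 0.012), a call lost without either untreated library or without replicate 1 of both treatments, at changes between 0.37 and 0.42.

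**Figure D1:**
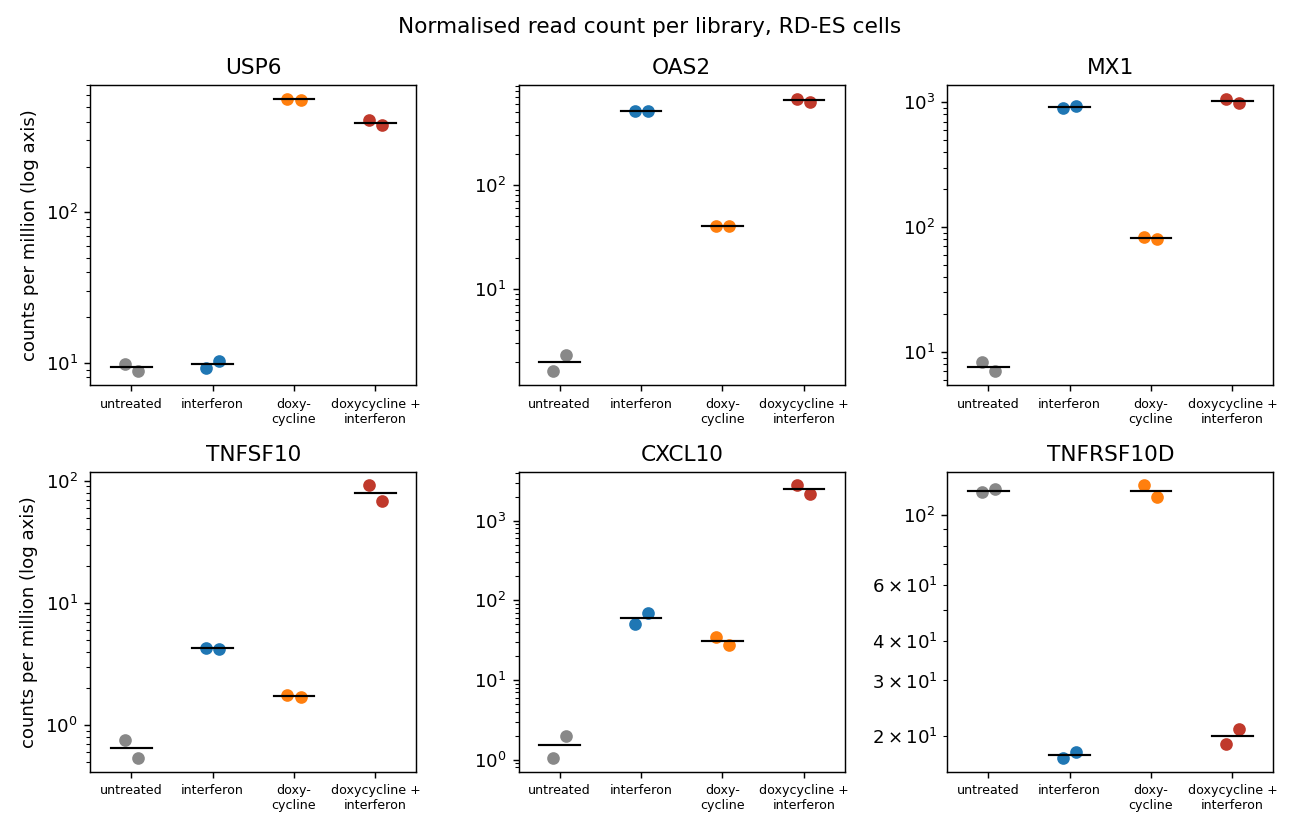
Normalised read counts (CPM, log axis) of USP6, OAS2, MX1, TNFSF10, CXCL10 and TNFRSF10D in each of the 8 libraries. Points are single libraries and lines are group means of 2 libraries; CXCL10 rose from 1.51 CPM in untreated cells to 2480 CPM with both treatments, and TNFRSF10D stood near 119 CPM without interferon and at 17.4 and 20 CPM with it.

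The response to interferon alone was asked for by comparing interferon-treated with untreated cells. OAS2, which makes the 2-5A activator of RNase L, rose from 1.97 ± 0.504 to 512.9 ± 2.66 CPM (log2 8.01 ± 0.14, edgeR adjusted p = 7.6e-11). The dynamin-like antiviral GTPases MX1 and MX2 rose by 6.90 ± 0.12 and 6.75 ± 0.16, and the interferon-induced genes IFI27 and IFI6 by 7.85 ± 0.18 and 5.92 ± 0.12. CASP1, the caspase that processes interleukin 1 beta, had 0 reads in untreated cells and 88 with interferon, at least 31.1-fold higher against a floor of 3 reads over the group (16 and 15.1 without untreated replicates 1 and 2). TNFRSF10D, a decoy receptor for the death ligand TRAIL, had the lowest fold change of the genes named by rule, at 17.4 ± 0.521 against 119.5 ± 1.63 CPM (log2 -2.78 ± 0.11, edgeR adjusted p = 2e-08).

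All 62 tested members of the interferon-stimulated gene list rose, over all genes and also adjusted over the list alone. Their median log2 change was 3.24, or 3.20 with RTP4, which had 0 untreated reads, at its bound (camera adjusted p = 2.4e-130). RTP4, with 14 reads on interferon, was at least 4.94-fold higher (2.55 and 2.4 without untreated replicates 1 and 2). It lost its call without either library of the untreated, interferon or both-treatments groups. Of 22 JAK-STAT genes 4 rose and 18 were not called, with 5 called adjusted over the list alone (camera adjusted p = 0.00013). Among them were the transcription factors STAT2 (2.31 ± 0.12) and IRF9 (3.40 ± 0.15), and the feedback protease USP18 (2.83 ± 0.15). JAK1 changed by 0.14 ± 0.10 and STAT3 by 0.30 ± 0.08, and neither was called. Of 19 IRF and GAS-type targets 15 rose, with 18 adjusted over the list alone (median 2.27, camera adjusted p = 1e-35), among them the guanylate-binding protein GBP1 (2.90 ± 0.12) and the chemokine CXCL10 (5.30 ± 0.30). Of 20 genes for MHC class I antigen presentation 16 rose, with 17 adjusted over the list alone (median 1.62, camera adjusted p = 1.1e-34). They included the peptide transporter TAP1 (3.53 ± 0.13) and the class I chain HLA-B (3.24 ± 0.12), whose reads can be split with other HLA genes. With an estimated correlation the camera adjusted p was much larger for these 4 lists. It was 0.0037 for interferon-stimulated genes, 0.04 for JAK-STAT, 0.0095 for IRF and GAS-type targets and 0.016 for class I presentation.

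In the death receptor list 1 gene rose, 1 fell and 18 were not called, with 4 higher and 1 lower adjusted over the list alone. The list passed camera at an adjusted p = 0.00065 and had an adjusted p = 0.06 with an estimated correlation. TNFSF10, which encodes TRAIL, rose from 0.648 ± 0.158 to 4.25 ± 0.0565 CPM (log2 2.70 ± 0.33, edgeR adjusted p = 0.00067). The TRAIL receptors TNFRSF10A (-0.05 ± 0.18) and TNFRSF10B (0.21 ± 0.09) were not called. Of 20 NF-kB targets 3 rose, with 6 adjusted over the list alone (camera adjusted p = 2.3e-08): the inhibitor NFKBIA by 1.06 ± 0.09 and the adhesion molecules VCAM1 and ICAM1 by 1.33 ± 0.26 and 1.32 ± 0.26. VCAM1 lost its call without any untreated or interferon library (between 1.3 and 1.37), and ICAM1 without untreated replicate 2 or either interferon library (between 0.96 and 1.8). Of 23 genes of the ATF4 amino acid response 8 rose, with 17 adjusted over the list alone (median 0.45, camera adjusted p = 2.1e-13, adjusted p = 0.046 with an estimated correlation). They included CHAC1, which degrades glutathione (2.53 ± 0.27), and ASNS, asparagine synthetase (0.77 ± 0.10). Of 12 chemokines 3 rose, with 5 adjusted over the list alone (camera adjusted p = 2.3e-08). Their median of 2.32 depended on genes at 0 reads, and was 0.85 with these at their bound. Over the 6 genes with more than 3 reads in both groups it was 0.255. CCL5 was 13.8-fold higher by reads, 26 against 2 (95% counting interval 3.45 to 120), at least 4.73-fold without untreated replicate 1 and 6.68-fold (1.67 to 58.1) without untreated replicate 2.

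Replication-dependent histones fell. Of 18 tested 13 fell, with 17 adjusted over the list alone, at a median of -0.79 and -0.65 after a correction for GC content and length (camera adjusted p = 8.2e-18, adjusted p = 0.12 with an estimated correlation). HIST1H4C fell from 546.9 ± 38.2 to 206.8 ± 23 CPM (log2 -1.40 ± 0.10, edgeR adjusted p = 5.3e-06) and HIST1H3B by 1.2 on the log2 scale. Histone genes are near-identical copies, so the value of a single member is uncertain. Of 30 cell cycle genes 4 fell, with 21 adjusted over the list alone (median -0.37, camera adjusted p = 8.3e-12). These were RRM2 and RRM1, subunits of ribonucleotide reductase, the cyclin CCNE2 and the replicative helicase subunit MCM2, with changes between -0.71 and -0.44. None of 32 ribosomal protein genes was called over all genes or adjusted over the list alone, at an unadjusted p under 0.05 for 1700 genes of the whole comparison. Their median was -0.19 (camera adjusted p = 3.7e-07).

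In total 237 genes rose and 73 fell with interferon alone, and with the correction for GC content and length the split was 470 and 281. The count of 310 became 177 without untreated replicate 2, 174 without interferon replicate 1 and 177 without interferon replicate 2. Of 55 named genes called, 36 kept their call without each library in turn; RRM2 (between -0.71 and -0.45) and CCNE2 (-0.93 and -0.52) lost it without untreated replicate 2 or interferon replicate 1, MCM2 (-0.57 and -0.44) without any untreated or interferon library, RRM1 (-0.51 and -0.36) also without either doxycycline library, and CCL5 without untreated replicate 2, either interferon library, doxycycline replicate 1 or either library of both treatments.

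The effect of switching on USP6 was asked for by comparing doxycycline-treated with untreated cells. OAS2 rose from 1.97 ± 0.504 to 40.67 ± 0.179 CPM (log2 4.35 ± 0.16, edgeR adjusted p = 8.6e-08), MX1 by 3.43 ± 0.12 and the chemokine CXCL10 by 4.35 ± 0.31 (edgeR adjusted p = 2.6e-05). SELE, the endothelial adhesion molecule E-selectin, had 0 reads in untreated cells and 78 with doxycycline, at least 23.8-fold higher (12.2 and 11.5 without untreated replicates 1 and 2). TNFRSF9, a co-stimulatory receptor of the TNF family, was 107-fold higher by reads, 117 against 1 (95% counting interval 18.8 to 4260). That read lay in untreated replicate 1, without which the fold was at least 18.3, and without untreated replicate 2 it was 51.9 (9.13 to 2070).

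Of the 62 interferon-stimulated genes 42 rose, with 54 adjusted over the list alone. Their median was 1.24, or 1.19 with genes at 0 reads at their bound (camera adjusted p = 2.6e-60). Of 22 JAK-STAT genes 3 rose, IRF9 (2.17 ± 0.16) and STAT2 (0.85 ± 0.12) among them, and 19 were not called, with 5 called adjusted over the list alone (camera adjusted p = 1.2e-05). Of 19 IRF and GAS-type targets 8 rose, with 15 adjusted over the list alone (median 1.35, camera adjusted p = 6.6e-22), among them GBP1 (1.35 ± 0.12) and GBP2 (2.05 ± 0.21). Of 20 class I presentation genes 4 rose, with 11 adjusted over the list alone, including TAP1 (1.2 ± 0.13). That list passed camera at an adjusted p = 4.3e-09 and had an adjusted p = 0.13 with an estimated correlation. Of 20 NF-kB targets 5 rose, with 13 adjusted over the list alone (median 0.89, camera adjusted p = 1.8e-12). They included NFKBIA (1.28 ± 0.09) and the adhesion molecule ICAM1 (1.84 ± 0.25). Of these 5 genes only NFKBIA kept its call without each library in turn. NFKB1 (0.79 to 0.93) lost it without either untreated library or doxycycline replicate 1. IL8, also counted among the chemokines, lost it without each library in turn. The ATF4 amino acid response also rose with doxycycline, in 3 of 23 genes, with 8 adjusted over the list alone (median 0.22). That list passed camera at an adjusted p = 1.3e-05 and had an adjusted p = 0.17 with an estimated correlation. ASNS rose by 0.88 on the log2 scale (0.83 to 0.92 over the libraries left out) and CHAC1 by 1.75 (1.66 to 1.82). CHAC1 lost its call without either untreated or either doxycycline library. ATF3, the other gene called, rose by 0.94 (0.76 to 1.11) and lost its call without each library in turn. Of 12 chemokines 5 rose, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.4e-10). Their median was 3.62, and 2.15 with genes at 0 reads at their bound. Over the 6 genes with more than 3 reads in both groups it was 0.664. IL8 (25 reads against 2) and CCL4 (20 against 1) lost their calls without each library in turn. CXCL11 (3.92 to 4.02) lost its call without untreated replicate 2. CCL5 was 21.5-fold higher by reads, 47 against 2 (95% counting interval 5.62 to 183), at least 7.37-fold without untreated replicate 1 and 10.4-fold (2.73 to 88.6) without untreated replicate 2.

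TNFSF10 changed by 1.40 ± 0.39 (edgeR adjusted p = 0.15), and in the death receptor list 1 gene, the apoptosis inhibitor BIRC3, rose, with 3 adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.17 with an estimated correlation). TNFRSF10D stood at 119.1 ± 7.01 CPM, a change of 0.00 ± 0.09. Of 18 histone genes 1 fell, with 16 adjusted over the list alone (median -0.55, camera adjusted p = 8.8e-12, adjusted p = 0.2 with an estimated correlation). The gene, HIST1H2AB, lost its call under the correction for GC content and length. Of 30 cell cycle genes 0 were called by edgeR, with 1 lower adjusted over the list alone, at an unadjusted p under 0.05 for 1992 genes of the whole comparison. Among the few genes that fell were TUBB3, a neuronal tubulin (-1.30 ± 0.24, edgeR adjusted p = 0.037), and the keratin KRT17 (-1.2 ± 0.19, edgeR adjusted p = 0.016).

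In total 105 genes rose and 14 fell with doxycycline alone. The split was 290 and 193 with the correction for GC content and length and 144 and 95 by DESeq2 with its own size factors. The lower calls were all lost without untreated replicate 2 or without doxycycline replicate 1. The count of 119 became 54 without untreated replicate 2, 78 without interferon replicate 2 and 70 without doxycycline replicate 1. Of 41 named genes called, 19 kept their call without each library in turn; TUBB3 (between -1.62 and -1.04) and KRT17 (-1.42 and -1) lost it without any untreated or interferon library or doxycycline replicate 1, BIRC3 (0.82 and 1.22) also without doxycycline replicate 2, HIST1H2AB (-0.78 and -0.66) without any untreated or doxycycline library, ICAM1 (1.45 and 2.32) without untreated replicate 2, and CCL5 without untreated replicate 2 or doxycycline replicate 2.

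The response to interferon in doxycycline-treated cells was asked for by comparing both treatments with doxycycline alone. The chemokine CXCL10 rose from 31.3 ± 5.07 to 2480 ± 430 CPM (log2 6.31 ± 0.21, edgeR adjusted p = 1.1e-08), CXCL11 from 3.07 ± 0.1 to 318.3 ± 66.2 CPM (6.69 ± 0.18), CXCL9 by 6.18 ± 0.23 and CCL8 by 7.30 ± 0.34 (8.05 and 6.82 without doxycycline replicates 1 and 2). IDO1, which degrades tryptophan, rose by 6.25 ± 0.25, and MMP13, a collagenase, by 6.01 ± 0.46 (5.42 and 6.97 without doxycycline replicates 1 and 2). The value of 6.97 rests on 2 reads left with doxycycline, so its size is uncertain. TNFSF10 rose from 1.73 ± 0.0368 to 79.96 ± 16.8 CPM (5.52 ± 0.22, edgeR adjusted p = 3.6e-08). TNFRSF10D fell to 20 ± 1.57 CPM (-2.58 ± 0.11, edgeR adjusted p = 4.9e-08).

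All 62 interferon-stimulated genes rose, over all genes and adjusted over the list alone (median 2.33, camera adjusted p = 3.3e-99). IFI27 rose by 5.54 ± 0.14 and MX2 by 4.80 ± 0.12, while RTP4 was 67-fold higher by reads, 162 against 3 (95% counting interval 22.5 to 329). All 19 IRF and GAS-type targets rose, over all genes and adjusted over the list alone (median 3.46, camera adjusted p = 2.4e-41), GBP1 by 3.46 ± 0.11 and GBP5 by 5.74 ± 0.30. Of 20 class I presentation genes 16 rose, with 18 adjusted over the list alone (camera adjusted p = 5.8e-30), and of 22 JAK-STAT genes 5 rose, with 6 adjusted over the list alone (camera adjusted p = 3.9e-06). Of 20 NF-kB targets 13 rose, with 16 adjusted over the list alone (median 1.40, camera adjusted p = 2.8e-18), including ICAM1 (2.19 ± 0.20) and the chemokine CCL2 (2.27 ± 0.22). Of 12 chemokines 9 rose, with 10 adjusted over the list alone (median 2.94, camera adjusted p = 7.3e-20). In the death receptor list 6 genes rose and 1 fell, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.9e-08). The apoptosis inhibitors BIRC3 (1.59 ± 0.17) and BIRC2 (0.64 ± 0.10) were among those that rose.

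Of 18 histone genes 16 fell, with 18 adjusted over the list alone, at a median of -0.89 and -0.65 after the correction for GC content and length (camera adjusted p = 1.7e-17, adjusted p = 0.12 with an estimated correlation). HIST1H4C fell by 1.51 on the log2 scale and HIST1H3B by 1.32. Of 30 cell cycle genes 9 fell, with 21 adjusted over the list alone (median -0.44, camera adjusted p = 6.9e-11), RRM2 by 0.65 on the log2 scale. In total 354 genes rose and 132 fell. The count of 486 became 318 without doxycycline replicate 1 and 290 without replicate 2. Of 64 named genes called, 47 kept their call without each library in turn, and BIRC2 lost it without doxycycline replicate 2, with changes between 0.52 and 0.78 over the libraries left out.

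**Figure D2:**
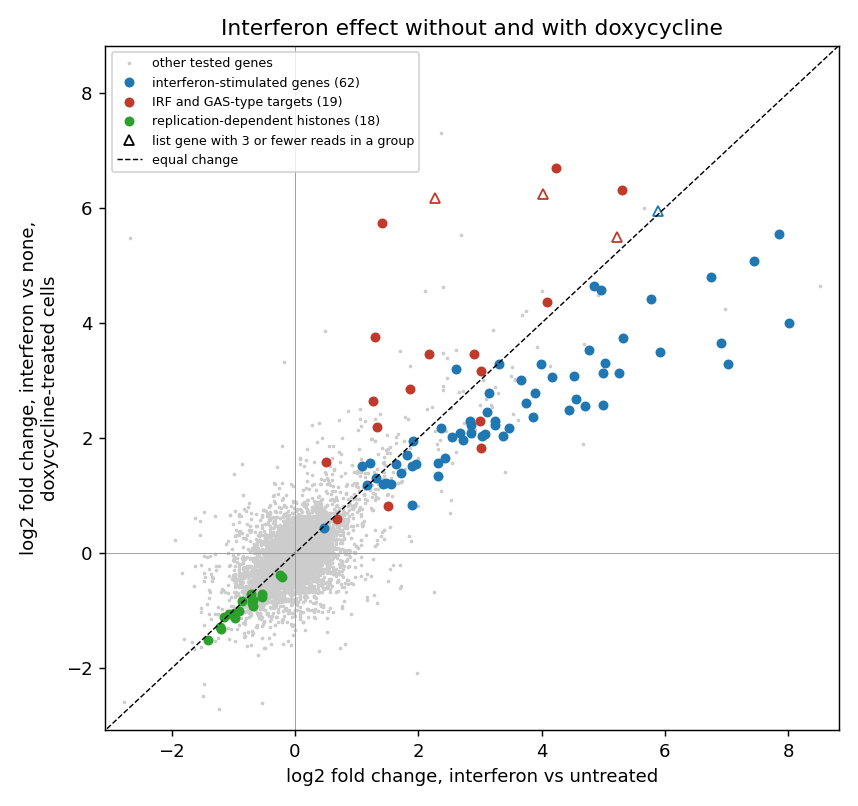
Log2 fold change with interferon in cells without doxycycline (horizontal) against that in doxycycline-treated cells (vertical), 1 point per tested gene from 2 libraries per group, with members of 3 gene lists in colour. Open triangles mark list genes with 3 or fewer reads in a group, whose position depends on the prior count; OAS2 lies at 8.01 and 4.01, below the line of equal change, and CXCL11 at 4.23 and 6.69, above it.

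The responses to interferon without and with doxycycline share no library, but they share the dispersion estimate of the 1 fit. They had 208 genes called higher in common, of 237 and 354, against 5.75 expected of independent lists, and 61 called lower, of 73 and 132, against 0.66 (Fisher's exact test for the latter, two-sided, p = 2.4e-119). No gene was called in opposite directions. Across the 527 genes called in either the log2 changes had a Pearson r of 0.864 and a Spearman's rho of 0.919. Genes are not independent replicates, for these values or for Fisher's test.

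The effect of doxycycline in interferon-treated cells was asked for by comparing both treatments with interferon alone. The chemokine CXCL11 rose by 6.44 ± 0.18 (edgeR adjusted p = 1.1e-08), CXCL9 by 6.88 ± 0.25 and CXCL10 by 5.36 ± 0.20, while CCL8 was 994-fold higher by reads, 928 against 1 (95% counting interval 178 to 39300), at least 169-fold without interferon replicate 1 and 487-fold (87.1 to 19200) without interferon replicate 2. CCL20 was 38.9-fold higher by reads, 109 against 3 (95% counting interval 13 to 192). TNFSF10 rose by 4.23 ± 0.19 (edgeR adjusted p = 7.2e-07), and IDO1 by 4.32 ± 0.21. SELE rose by 7.25 ± 0.43 and MMP13 by 5.23 ± 0.43. Without interferon replicate 1 the fitted changes were 6.32 and 4.53, and without interferon replicate 2 they were 11.4 and 6.73. In the latter fit MMP13 had 2 reads left with interferon, so its value depends on the prior count. The SELE value of 11.4 is likewise uncertain in size.

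Of 12 chemokines 9 rose, and 9 did adjusted over the list alone (median 4.6, camera adjusted p = 2.2e-20). Of 19 IRF and GAS-type targets 15 rose, with 17 adjusted over the list alone (median 2.12, camera adjusted p = 6.5e-31). Of 20 NF-kB targets 14 rose, with 16 adjusted over the list alone (median 1.5, camera adjusted p = 4.4e-21), including NFKBIA (1.56 ± 0.09), ICAM1 (2.70 ± 0.21) and CCL2 (3.20 ± 0.24). In the death receptor list 3 genes rose, TNFSF10, BIRC3 (1.88 ± 0.18) and BIRC2 (0.89 ± 0.10), with 6 adjusted over the list alone (camera adjusted p = 2.2e-07). Of the 62 interferon-stimulated genes 15 rose and 47 were not called, with 32 higher adjusted over the list alone (median 0.30, camera adjusted p = 4.2e-14). The antiviral genes IFIT2 (2.30 ± 0.11), OASL (1.97 ± 0.16) and RSAD2 (1.34 ± 0.11) rose, while MX1 (0.17 ± 0.09) and OAS2 (0.35 ± 0.09) were not called. Of 22 JAK-STAT genes 1 rose, STAT5A, with 8 adjusted over the list alone (camera adjusted p = 3.9e-05). Of 20 class I presentation genes 3 rose, with 11 adjusted over the list alone, TAP1 by 0.91 ± 0.10 (camera adjusted p = 7.1e-06, adjusted p = 0.15 with an estimated correlation). Of 18 histone genes 8 fell, with 18 adjusted over the list alone (median -0.63, camera adjusted p = 2.7e-13, adjusted p = 0.17 with an estimated correlation).

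In total 156 genes rose and 40 fell. The split was 194 and 108 by DESeq2 with its own size factors, and 447 and 115 with the correction for GC content and length. The lower calls, histone genes included, were all lost without interferon replicate 2 or without replicate 1 of both treatments. The named histone genes kept negative changes over the libraries left out, such as HIST1H4B (between -0.88 and -0.55). The count of 196 became 57 without interferon replicate 1, 46 without interferon replicate 2 and 75 without replicate 1 of both treatments. Of 49 named genes called, 25 kept their call without each library in turn, and STAT5A lost it without either interferon library or without replicate 2 of both treatments, at changes between 1.49 and 1.93. Doxycycline without and with interferon had 48 genes called higher in common, of 105 and 156, against 1.12 expected of independent lists, and 5 called lower, of 14 and 40, against 0.04.

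**Figure D3:**
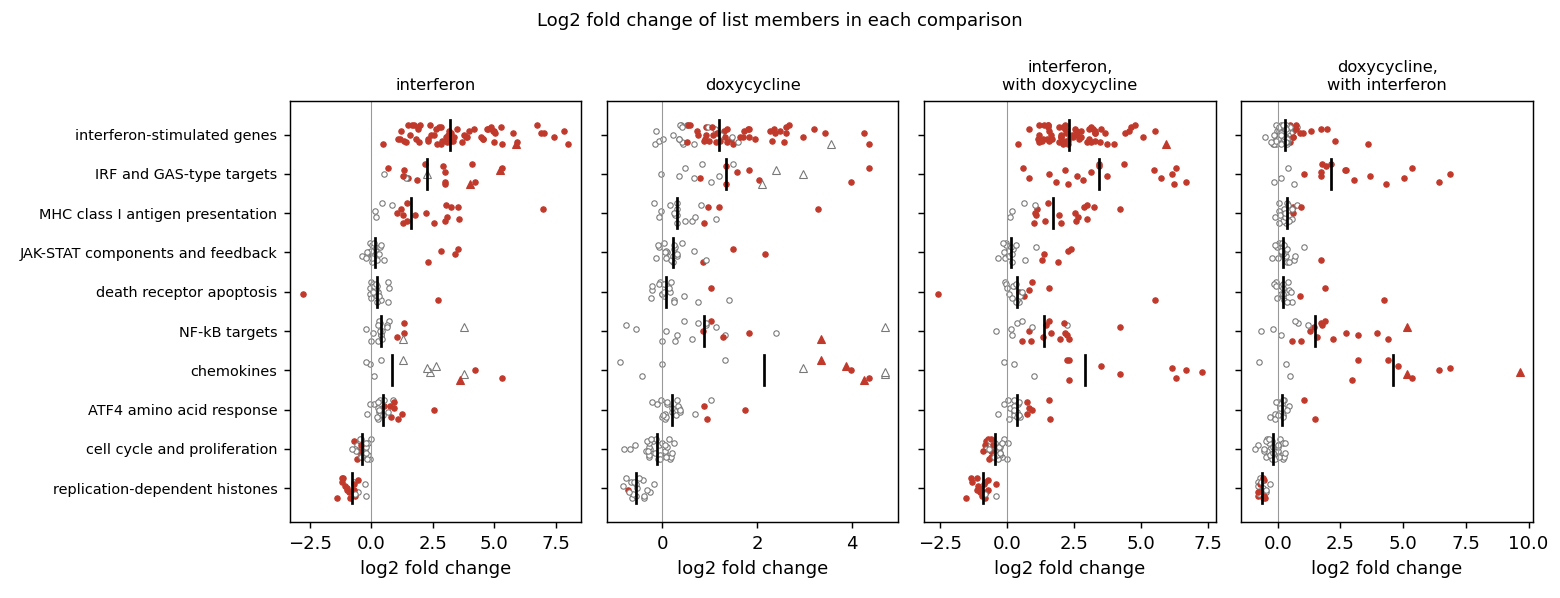
Log2 fold changes of the tested members of 10 gene lists in the 4 comparisons of single treatments, from 2 libraries per group. Filled points passed the edgeR test, open ones did not, triangles mark genes with 3 or fewer reads in a compared group, and bars are medians with genes at 0 reads set at their bound; the interferon-stimulated genes had medians of 3.20, 1.19, 2.33 and 0.30 from left to right.

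Whether the response to interferon differed with doxycycline was tested by the interaction. On the log2 scale the response of many interferon-stimulated genes was smaller with doxycycline, and that of chemokines and of IRF and GAS-type targets larger as lists. OAS2 had an interaction of -4 ± 0.19 and MX1 of -3.25 ± 0.15 (edgeR adjusted p = 2.1e-06 for each), IFI6 of -2.42 ± 0.15 and OAS1 of -2.43 ± 0.15. IRF9 had -1.99 ± 0.20 (edgeR adjusted p = 0.0014). WARS, the tryptophanyl-tRNA synthetase, was the only gene called in the other direction, at 1.07 ± 0.17 (edgeR adjusted p = 0.041).

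Of the 62 interferon-stimulated genes 22 had a lower response and 40 were not called, with 42 lower adjusted over the list alone (median -0.77, camera adjusted p = 1.2e-55). Levels of MX1 with both treatments, 1030 ± 56.9 CPM, were not below those with interferon alone, 913.1 ± 20.4 CPM. Among 19 IRF and GAS-type targets 1 was higher, WARS, with 9 higher and 3 lower adjusted over the list alone (median 0.99, and 0.93 over the 16 genes with more than 3 reads in every group, camera adjusted p = 9.6e-21). No chemokine passed the edgeR test over all genes, and 1 did adjusted over the list alone, CCL2 at 1.87 ± 0.39, at an unadjusted p under 0.05 for 287 genes of the whole comparison (median 0.96, camera adjusted p = 1.1e-26). For interferon without doxycycline only 6 of the 12 had more than 3 reads in both groups. The chemokine median thus depends on the prior count. No NF-kB target passed over all genes and 5 did adjusted over the list alone (median 0.65, camera adjusted p = 4.9e-17). In the death receptor list 0 passed over all genes by edgeR and 1 adjusted over the list alone, TNFSF10 at 2.83 ± 0.51 (edgeR adjusted p = 0.089 over all genes; list median 0.16, camera adjusted p = 2.2e-06). Of 22 JAK-STAT genes 2 were lower, IRF9 among them, and the list did not pass camera (adjusted p = 0.51).

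In total 1 gene was called higher and 24 lower, against 12 and 42 with the correction for GC content and length, 7 and 35 by DESeq2, and 4 and 22 with summed rows. The count of 25 became 15 and 11 without untreated replicates 1 and 2, 9 and 14 without interferon replicates 1 and 2, and 14 without doxycycline replicate 1. WARS lost its call without 7 of the 8 libraries, all but interferon replicate 2, between 0.92 and 1.26.

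Both treatments against none gave the widest change. CXCL10 rose by 10.66 ± 0.28 and CXCL11 by 10.67 ± 0.27 (edgeR adjusted p = 7.4e-10 and 6e-10), and CCL8, with 0 untreated reads and 928 with both treatments, was at least 351-fold higher (181 and 170 without untreated replicates 1 and 2). MMP13 was at least 163-fold higher (83.7 and 78.9 without them), and CXCL9 639-fold by reads, 1127 against 2 (95% counting interval 177 to 5290). TNFSF10 rose by 6.93 ± 0.25 and its receptor TNFRSF10B by 0.59 ± 0.09, while TNFRSF10D fell by 2.58 on the log2 scale. STAT2 rose by 2.76 ± 0.12, IRF9 by 3.57 ± 0.15 and STAT3 by 0.52 ± 0.08, and JAK1 (0.10 ± 0.10) and TNFRSF10A (0.15 ± 0.18) were not called.

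Of the 62 interferon-stimulated genes 61 rose, with 62 adjusted over the list alone (median 3.60, camera adjusted p = 2.9e-76), and all 19 IRF and GAS-type targets did (median 4.81, camera adjusted p = 9.9e-32). Of 20 NF-kB targets 16 rose, with 18 adjusted over the list alone (camera adjusted p = 8.6e-17), and of 12 chemokines 9 rose, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.4e-14). In the death receptor list 12 genes rose and 1 fell, as also adjusted over the list alone (camera adjusted p = 4.5e-06). Of 30 cell cycle genes 17 fell, with 21 adjusted over the list alone (median -0.49, camera adjusted p = 2.4e-08), among them MCM2 (-0.92 ± 0.11) and the transcription factor E2F1 (-1.38 ± 0.19). All 18 histone genes fell (median -1.46, camera adjusted p = 4.1e-17, adjusted p = 0.13 with an estimated correlation). In total 1040 genes rose and 983 fell, and the split was 1866 and 912 with the correction for GC content and length. Among genes without a call, the log2 change fell with GC content here too, with a rho of -0.46, so the split is uncertain. The count of 2023 became 862 and 1018 without untreated replicates 1 and 2, and 712 without replicate 1 of both treatments.

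The comparisons of interferon alone and of doxycycline alone use the same untreated libraries. They had 79 genes called higher in common, of 237 and 105, against 1.7 expected of independent lists. In 50 simulations of unchanged groups against these controls at most 0 were shared, but few genes are called where nothing changed. Over all genes their log2 changes had a Pearson r of 0.587, against 0.502 on average and at most 0.524 in the simulations, and a covariance of 0.1087 against 0.0306. The 2 untreated libraries were not divided between the comparisons, which would leave 1 for each, so part of the excess may come from the shared controls. The simulations drew genes independently and held no trend with GC content. Among genes without a call, the real log2 changes fell with GC content in both comparisons, at a rho of -0.29 and -0.42. The excess over the simulated correlation and covariance therefore cannot be read as a shared response.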

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

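The interaction tests of genes and lists were planned, while the tests of library scaling and of a weaker interferon response were chosen only after the result was seen. The interferon effect differed with doxycycline, by the interaction test, in genes that the rule names in any comparison. The interaction log2 fold change was -4 for OAS2, -3.75 for EPSTI1, -3.25 for MX1, -2.43 for OAS1, -2.42 for IFI6, -2.36 for XAF1, -2.31 for IFI27, -2.14 for IFI44L, -2.13 for IFIT1, -1.99 for IRF9 and -1.94 for MX2, and it was 1.07 for WARS. XAF1 lost its call without each of the 8 libraries in turn, between -2.62 and -2.12, and IFI27 without 5 of them, either untreated library, either doxycycline library or interferon replicate 1, between -2.54 and -2.08. MX2 lost it without either untreated library or interferon replicate 1, between -2.06 and -1.81, and WARS without all libraries but interferon replicate 2, between 0.92 and 1.26.

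The effect also differed, by the set test of the interaction, in 5 lists that passed with a preset and with an estimated correlation. The median interaction was -0.768 for interferon-stimulated genes, 0.989 for IRF and GAS-type targets, 0.164 for death receptor apoptosis, 0.645 for NF-kB targets and 0.964 for chemokines. The chemokine value is uncertain, since only 6 of 12 genes had more than 3 reads in both groups for interferon without doxycycline.

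The smaller log2 response of interferon-stimulated genes with doxycycline was weighed. A fault of library scaling would move other interferon-raised lists the same way, but the median interaction of the IRF and GAS-type targets was 0.99. A weaker interferon response and a raised starting level cannot be told apart here. A difference in time on doxycycline, which is not stated for cells without interferon, cannot be separated from either. The median doxycycline effect in interferon-treated cells was 0.30, positive in 52 of 62 genes, but it was 1.24 without interferon, and from such a start a weaker response would also leave a positive value. A test of the raised start only restated the pattern and was set aside after its result was seen, and 1 dose and 1 time point give no separate test.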

How the results depend on the processing

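The crossed block, the marked rows and the correction for GC content and length were chosen after seeing the data. Over all alternatives, values of named genes stayed on the same side of the threshold 10692 times, passed it newly 370 times and lost it 599 times, and list tests did so 2546, 38 and 110 times. KRT18 with both treatments reversed, from -0.03, not called, to 0.33 under the GC and length correction. That correction gave 751 calls for interferon without doxycycline, 483 for doxycycline without interferon, 1376 for interferon with doxycycline, 562 for doxycycline with interferon, 54 for the interaction and 390 shared interferon calls. It kept 304 of the 310, 115 of the 119, 471 of the 486, 184 of the 196 and all 25 main calls in that order, and 1578 of 2023 for both treatments. DESeq2 gave 239 calls for doxycycline without interferon, 302 with interferon and 42 for the interaction. Doxycycline without interferon had 207 calls with no filter and 78 with only the groups compared. The cause was not tested. A minimum of 2-fold, which by construction removes calls, left 193, 66, 271 and 96 for the single treatments in the order above and 654 for both. With an estimated correlation 5 lists passed for doxycycline without interferon, 9 for interferon with doxycycline, 6 for doxycycline with interferon and 5 for the interaction, where fry also gave 5.

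Leaving out 1 library in turn, with fewer samples, gave 174 to 336 calls for interferon and 54 to 131 for doxycycline alone, 290 to 480 for interferon with doxycycline, 46 to 266 for doxycycline with interferon, 9 to 20 for the interaction and 712 to 2589 for both. Shared interferon calls ranged from 148 to 194, and the median interaction of interferon-stimulated genes from -0.844 to -0.684, and from -0.771 to -0.737 under the other settings with a set test, past the threshold in each. Lists passing ranged from 12 to 13, 10 to 13, 14 to 16, 10 to 15, 9 to 11 and 12 to 13.

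Same-numbered replicates shared only a number. Their deviations from the group means correlated by 0.34 between untreated and interferon and by 0.45 between the doxycycline groups, but by -0.35 to -0.12 across doxycycline. With the replicate block 244, 121, 408, 173, 17 and 1705 genes were called. The crossed pairing swapped replicate numbers in the doxycycline groups, matching the signs of the correlations above, so a lower residual spread was built in. It gave 1117, 1252, 1864, 1497, 53 and 4735 calls, and 453 shared interferon calls. Depth limited genes near the floor, such as the chemokines in untreated cells.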

Other observations

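Of the tests in this part, that of the cell cycle list was chosen only after the result was seen, as was the check on short genes. In the unfolded protein response list DDIT3, a pro-apoptotic transcription factor, was the only gene that rose with interferon, by 0.77 ± 0.11 (edgeR adjusted p = 0.0016), and by 0.72 ± 0.10 in doxycycline-treated cells. The list had adjusted p = 0.16 and 0.12 with an estimated correlation. Among 16 immediate early genes 3 rose with interferon in doxycycline-treated cells, ATF3 (1.63 ± 0.17), IER3 (1.46 ± 0.16) and the phosphatase DUSP6 (1.59 ± 0.25), with 7 adjusted over the list alone (camera adjusted p = 5.2e-07, adjusted p = 0.073 with an estimated correlation). In the BCL2 family PMAIP1, which encodes the pro-apoptotic protein NOXA, was the only gene called in each single-treatment comparison, and rose by 1.12 ± 0.09 with both treatments (edgeR adjusted p = 1.2e-05). With a single treatment it rose by 0.49 to 0.62, and these calls held without each library in turn only for interferon in doxycycline-treated cells. The others were lost without any untreated or interferon library for interferon alone (0.5 to 0.56) and also without either doxycycline library for doxycycline alone (0.44 to 0.55). Doxycycline in interferon-treated cells lost it without either interferon library or replicate 1 of both treatments (0.56 to 0.63). Of 33 targets activated by EWSR1-FLI1, the fusion oncogene of Ewing sarcoma, 3 rose and 4 fell with both treatments, and that list did not pass camera (adjusted p = 0.94). It passed camera downward with doxycycline alone (adjusted p = 8e-05, 0 genes called by edgeR and 7 lower adjusted over the list alone) and in interferon-treated cells (adjusted p = 0.049, 1 gene higher and 1 lower). It passed upward with interferon in doxycycline-treated cells (adjusted p = 0.00041, 4 genes higher) and for the interaction (adjusted p = 0.024, 0 genes called). None of these 4 held with an estimated correlation, at adjusted p = 0.17, 0.36, 0.12 and 0.38. CD68, a macrophage marker, rose with interferon by 1.83 ± 0.22 and by 2.34 ± 0.21 in doxycycline-treated cells, while the other 6 tested markers of immune cells were not called.

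Histone transcripts were lower in both interferon comparisons. A bias in GC content and transcript length was argued against by a correction for both, after which the median was -0.65 in place of -0.79 and 15 of 18 genes were called lower, against 13 before it. In doxycycline-treated cells the median was -0.65 in place of -0.89 and 15 genes were called lower, against 16. The correction raised the calls over all genes from 310 to 751 and from 486 to 1376. A loss of short transcripts was argued against by 3402 other genes of the same GC and length range, with a median of -0.04 and quartiles of -0.18 and 0.10. That range reached from 381 to 2250 nt, so it was not limited to short genes. A set of 237 short genes outside the histone families, of 300 to 700 nt, had a median of -0.09. The sets can overlap. A lower yield of short RNAs without poly-A tails stays open. RMRP changed by -0.47 ± 0.21 and RPPH1 by -0.55 ± 0.26 with interferon, and by -0.25 ± 0.21 and -0.36 ± 0.26 in doxycycline-treated cells, none of them called. The 7 tested small and structural noncoding RNAs had medians of -0.135 and 0.08 in these comparisons and did not pass camera (adjusted p = 0.38 and 0.6). Fewer cells in S phase may also explain the pattern, and this stays a hypothesis found and tested on the same data. With interferon alone the cell cycle list had a median of -0.37 with a negative change in 30 of 30 genes, of which 4 passed the edgeR test. With doxycycline alone the histones also fell, at a median of -0.55. There the cell cycle list had a median of -0.11, with 11 of 30 changes positive and 0 genes called. It did not pass camera (adjusted p = 0.071) but passed downward by fry (adjusted p = 0.026).

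The USP6 count was lower with interferon in doxycycline-treated cells. Read composition was argued against, since the change closest to 0 under other size factors, summed rows and the GC and length correction was -0.49. A single aberrant library was argued against, since without each doxycycline-treated library in turn the change closest to 0 was -0.45. No biological explanation was tested, and reads of the transgene and the cell's own USP6 could not be separated. Time on doxycycline may also differ between these groups.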
